A study of Homo sapiens with 4 samples.

How the data were processed

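DNA captured with biotin-tagged SVS-1 was measured in 2 libraries of A549 cells, replicates A and B, and each has an input library of the same letter, which was not analysed here. The labels call A and B biological replicates and do not say how their cultures were kept apart. Reads were demultiplexed with bcl2fastq 2.17, trimmed with Trimmomatic 0.36 and aligned with Bowtie2 2.2.5, and the genome build is hg38, per the submitters' processing notes, which give names and versions only. The peak caller, the use of the input and the treatment of reads that align to several places are not given in the sources used here. This matters in rDNA, which held 17.7% of the peaks of A and 13.4% of those of B and where an aligner can place a read in any of several copies; the share of other repeats was not measured. The deposited lists hold 1 row per peak with its positions and a score; there is 1 list per capture library, so the replicates could be compared. The score is the authors' own value per peak, its scale is not stated, no score is below 4, and each deposited list is sorted by it from high to low. It was used to rank, filter and compare peaks within a list, and for the correlation and its scatter over shared loci. Scores of A and B are set side by side in places, but no fold change of the score between replicates is given. Peak starts and ends lie on a grid of 100 bp windows in all 406 and 395 rows, with both ends included, and positions are given here counted from 1.

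Genes were taken from a RefSeq table of GRCh38 patch 14, the assembly of hg38, with 59792 genes. Of these, 831 listed in the coordinates of scaffolds or alternate loci were left out, except rDNA copies assigned to 2 scaffolds. The table does not name their scaffold, and the choice rests on the offset between peak and 18S gene seen on chromosome 21, with no separate check. The table gives neither strand nor exons. The planned classes of promoter, exon and intron were therefore replaced by within 1 kb of a gene end, gene body and outside genes, by the midpoint of the peak. Chromosome lengths came from GenomeInfoDb 1.38.1. No genome sequence was used here, so the 7 planned sequence features (such as GC content, G-quadruplex motifs and repeat share) and the distance to assembly gaps and centromeres were not run, and random placement could not leave out gaps. The rDNA regions are these 2 scaffolds, whole, and the stretches within 30 kb of an rDNA gene on chromosome 21.

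Peaks were called shared when they overlapped by at least 1 bp; overlapping peaks of both lists were joined into shared loci, scored by their highest peak in each list. Overlap, gene classes, gene lists, chromosome ends and gene-free stretches were tested by 10000 random placements of each peak on its own chromosome or scaffold with its width kept. For overlap, only the peaks of B were moved. Each scaffold was taken to end at the last peak of either list. Overlap was tested one-sided and the others two-sided, with smallest p-values of 0.0001 and 0.0002. Benjamini-Hochberg adjustment ran over the 3 gene classes, the 21 gene lists or the 24 chromosomes. Medians and correlations were tested with 100000 permutations (two-sided). Chromosomes were tested with the exact binomial test. A gene counted as having a peak when the peak overlapped its body or the 5 kb on either side. The threshold was 0.05 throughout. Tests over peaks treat peaks as units, and neighbouring peaks are not independent.

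The tests, the gene lists, the alternatives and the rule for the genes named were fixed before the data were examined. The rule takes shared loci in the order of their mean score percentile over both lists and names the protein-coding gene that holds the midpoint or lies within 5 kb, otherwise the non-coding gene, otherwise the nearest protein-coding gene with its distance, up to 25 genes, plus up to 5 members of each fixed list at a shared locus. Distances are to the nearest gene end, since the start of a gene is not told from its end without strand. Loci on scaffolds were named only in rDNA. Genes outside that rule (CACNA1C, BCAS3, NELL2 and RPS7, and those with isolated peaks), the coverage along the 45S gene and chromosome Y were chosen after their values were seen.

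Alternatives were overlap by at least 50% of both peaks, or within 1 kb or 10 kb; the top 50% of each list by score; assembled chromosomes only; 1 shift for all peaks of a chromosome or scaffold; 1 replicate alone; protein-coding genes only; a gene end window of 5 kb; class by any overlap; gene bodies only; and a limit of 5 Mb. Added after the data were seen were runs without rDNA, without the scaffold copies of rDNA (coverage and scores of the 45S unit), without chromosome Y, by clusters joined over up to 50 kb, with placement within clusters, and the gene-free stretch. The procedures were tested on simulated data with 20 runs each. With nothing planted, the overlap, class and list tests made 0 calls, the chromosome end test 1, the median test 2 and the correlation test 1. The simulated peaks were placed independently, as the placement tests assume, and lack the clusters of the real lists. These runs therefore do not give the rate of false calls for clustered peaks. With 30 shared peaks planted, overlap was called in 20 of 20 runs, within 3 of the planted number in all of them, and with 15 olfactory receptor genes planted that list was called in 20 of 20 and other lists in 0. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.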

Results

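SVS-1 is a cell-penetrating peptide, a cationic beta-hairpin that folds at the negatively charged surface of cancer cells. Its positions on the genome were mapped in A549, an established human lung adenocarcinoma line, by Chem-seq, in which a biotin-tagged compound is fixed to chromatin, captured on streptavidin with the DNA near it, and sequenced. Cells were exposed to 15 µM of the tagged peptide for 1 h at 37 °C, were replated overnight and were fixed for 15 min in 1% paraformaldehyde. The design has 2 capture libraries, replicates A and B, each with a matching input library of lysate DNA. Each capture library gave a list of peaks on hg38, and these 2 lists are the data described here. The 2 input libraries were not analysed here, so no background was measured beside the peaks. Read depth is not stated in the lists, and binomial intervals below cover counting error over peaks only.

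Replicate A had 406 peaks covering 417.8 kb and replicate B had 395 peaks covering 506 kb. The median peak was 600 bp wide in both lists, and the widest was 22600 bp in A and 12300 bp in B. The authors' peak score, whose scale is not stated, ran from 4.01 to 115.96 in A (median 6.73) and from 4.00 to 178.87 in B (median 6.94). Peaks were gathered in few places. Joined over gaps of up to 50 kb, 20 clusters of at least 10 peaks held 284 peaks of A (70.0%) and 293 peaks of B (74.2%). Of these clusters, 18 had peaks of both replicates and 2, both on chromosome Y, had peaks of B only. Scaffolds that are not part of an assembled chromosome held 151 peaks of A (37.2%) and 112 of B (28.4%).

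Where the strongest peaks lay was the first question. The ribosomal RNA genes (rDNA), which encode the 45S precursor of the 18S, 5.8S and 28S ribosomal RNAs, held the highest-scoring peaks of B and most of the highest of A. The annotation used here places 4 copies of the 18S gene or of its pseudogenes on chromosome 21. Each of these 4 had a peak in both replicates that began between 4741 and 4875 bp before the 18S gene, which is upstream of the 45S start in the 3 complete copies there. Another 4 copies are annotated in scaffold coordinates without a scaffold name. They were assigned to a chromosome 22 scaffold and to a scaffold with no chromosome because peaks then stand at a like offset, so for these the offset is no finding and their gene parts rest on that choice. With them, the 8 peaks scored 92.6 ± 6.70 in A (SD over the 8 copies) and 164 ± 8.25 in B, and the 4 on chromosome 21 scored 92.4 ± 3.87 and 159 ± 6.69. The 8 ranked 1 to 8 of the 395 peaks in B and no lower than 11 of the 406 in A. On chromosome 21 they covered positions 8204801 to 8210000 at RNA45SN2, 8387901 to 8391700 at RNA45SN3, 8432001 to 8436300 at RNA45SN1 and 8249001 to 8253300 at RNA18SP5, where the microRNA gene MIR6724-2 also lies. The copies so assigned were RNA45SN4 and RNA18SP4 on the chromosome 22 scaffold, and RNA45SN5 and RNA18SP3 on the scaffold with no chromosome. The copies are nearly identical and can share reads, so their spread is not an error between independent loci.

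Coverage was uneven along the 5 complete 45S genes. In replicate A, peaks covered 100% of the 1 kb upstream of the 45S start, 82.6% ± 6.12 (SD over 5 copies) of the 5′ external transcribed spacer and 1.06% ± 2.37 of the 18S gene. The internal spacers with the 5.8S gene were covered to 81.0% ± 8.76 and the 28S gene to 41.5% ± 10.3. In replicate B the 18S gene was covered to 95.5% ± 9.45 and the 28S gene to 88.5% ± 4.29, against 92.4% ± 7.50 of the 5′ external transcribed spacer. On chromosome 21 alone (3 copies), the 18S gene was covered to 0% in A and 92.9% ± 12.4 in B, and the 28S gene to 40.7% ± 13.9 and 88.1% ± 5.93. In both replicates the score was highest at the promoter end of the unit. The highest peak that lay wholly between 1 kb before the 18S gene and the 28S end scored 12.32 to 14.62 over the 5 copies in A, below promoter peaks of 88.58 to 104.79. In B it scored 24.51 to 31.34 over 4 copies, below promoter peaks of 149.64 to 166.15. RNA45SN4 had no separate peak there in B, because 1 peak of 12300 bp ran from the promoter into the 28S gene. A further peak ran over the 28S end in all 5 copies. It scored 50.64 in RNA45SN1, 32.87 in RNA45SN2, 14.42 in RNA45SN3, 63.09 in RNA45SN4 and 19.79 in RNA45SN5 in A, and 98.91, 98.40, 49.14, 135.92 and 80.16 in the same order in B. In A, RNA45SN5 had another peak past that end, with a score of 33.56.

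**Figure D1:**
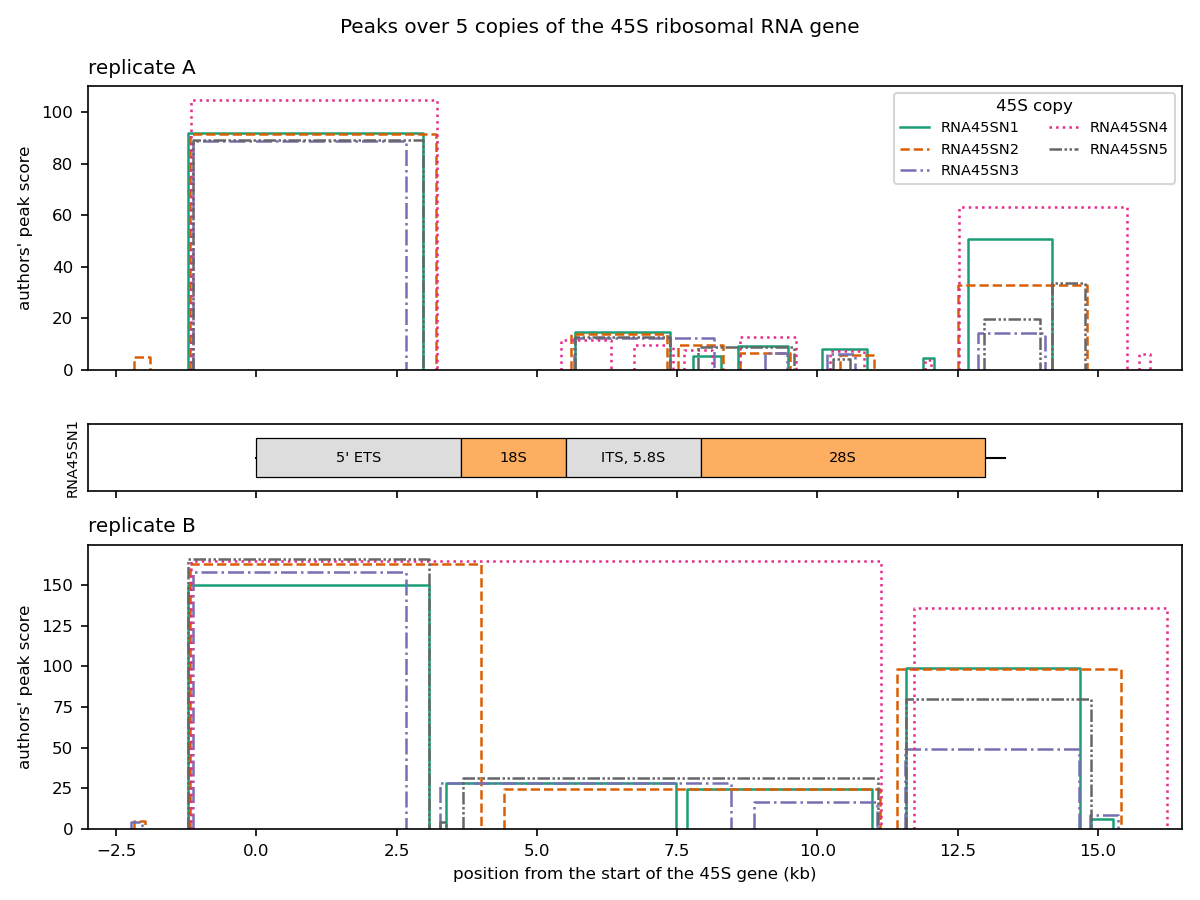
Peaks of replicate A (top) and replicate B (bottom) over 5 copies of the 45S gene, drawn as boxes from peak start to peak end with the authors' score as height, against the position from the 45S start in kb; the middle track shows the parts of RNA45SN1, and RNA45SN4 and RNA45SN5 are drawn as assigned to scaffolds. All 5 copies have their highest peak over the promoter and the 5′ external transcribed spacer, and the 18S gene is covered to 1.06% in A and 95.5% in B.

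Outside rDNA, the strongest shared peaks on assembled chromosomes lay mostly within 5 Mb of the longest gene-free stretch of their chromosome and far from any protein-coding gene. That stretch holds the centromere on most chromosomes, but centromere positions were not used here. Distances in this paragraph are to the nearest gene typed as protein-coding, and genes of other types were passed over. On chromosome 5 such peaks stood at 49599501 to 49603200 and 49656201 to 49662100, with scores of 104.26 and 115.96 in A and 76.44 and 74.15 in B; the nearest protein-coding gene was EMB, which encodes the cell adhesion protein embigin, 794.8 and 737 kb away. On chromosome 4 a cluster at 49091101 to 49156700 covered 54.4 kb in A and 48.0 kb in B, with top scores of 82.81 and 63.70. The protein-coding gene nearest to it was CWH43, between 41.2 and 92.6 kb from the named peaks. On chromosome 16, at the edge of the long heterochromatic block beside the centromere, the peak at 46385901 to 46392500 scored 59.74 in A and 81.99 in B, 189 kb from SHCBP1. A second place on chromosome 16, at 34581001 to 34584100, lay 193 kb from LOC124903767. On chromosome 1, whose centromere also borders such a block, peaks at 125178301 to 125181100 (58.52 and 63.25, 3717 kb from LINC02798) and 143214001 to 143215900 (27.55 and 22.49, 687 kb from the histone gene H3-7) stood on both sides of it. Peaks within 5 Mb of the longest gene-free stretch were also found on chromosome 10 at 41859201 (714 kb from the zinc finger gene ZNF33B), on chromosome 17 at 26880601 (411 kb from WSB1), on chromosome 20 at 31059301 (190 kb from the beta-defensin gene DEFB115) and on chromosome 21 at 10692201 (87.0 kb from TPTE, which encodes a testis phosphatase-like protein). A scaffold with no chromosome held 2 more of the strongest loci, with scores of 74.01 and 69.57 in A and 75.79 and 57.58 in B, for which no gene was named.

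Outside rDNA, few of the strongest shared peaks touched a gene. The peak on chromosome 4 at 190177401 to 190180200 lay inside DUX4, the transcription factor gene of the D4Z4 repeat array near the chromosome end, and scored 41.12 in A and 26.97 in B. The peaks on chromosome 2 at 89827801 to 89841200 lay inside IGK, the immunoglobulin kappa locus, with a top score of 40.96 in A and 37.37 in B. FAM230C on chromosome 13 and ROCK1P1 on chromosome 18, a non-coding RNA gene and a pseudogene, held peaks that scored 43.40 and 43.94 in A and 47.79 and 33.76 in B. FAM230E on chromosome 22 lay 3.33 kb from the midpoint of a peak that scored 52.05 and 55.52. On chromosome 21, MIR10396A lay 0.167 kb from the midpoint of a peak (20.48 and 35.77) and the pseudogene EIF3FP1 lay 4.89 kb from another (17.03 and 31.17). These loci were taken in the order of their mean score percentile over both lists, and no test was made of single loci.

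How far the replicates called the same places was asked next. The rDNA copies and the clusters on chromosomes 1, 4, 5, 10 and 16 were called in both, while the clusters on chromosome Y were called in B only. At least 1 bp was shared by 269 of the 406 peaks of A (66.3%, 95% Clopper-Pearson interval 61.4 to 70.8) and by 259 of the 395 peaks of B (65.6%, 60.7 to 70.2). The shared stretches covered 322.8 kb, which was 77.3% of the length called in A and 63.8% of that in B. They formed 227 shared loci, of which 34 were in rDNA and 193 elsewhere. Sharing rose with the score: of peaks in A scoring 4 to 5, 26.1% were shared, against 71 of the 72 peaks scoring 10 to 20 and all 51 peaks of at least 20. In B outside chromosome Y the same classes gave 40.4%, 55 of 56 and 57 of 57. For random placement, each peak of B was moved on its own chromosome or scaffold and the peaks of A stayed fixed. This gave 7.48% for A and 7.54% for B, and none of 10000 placements reached the observed overlap (one-sided placement test, n = 406 and n = 395 peaks, p = 1e-04 for both, the smallest these can give). On assembled chromosomes only, placement gave 0.072% for A and 0.050% for B, against 67.1% and 61.1% observed, so the share by placement came mostly from scaffolds. When the peaks of B were placed only within their own cluster, a test chosen after the data were seen, placement gave 40.8% for A and 50.1% for B (n = 406 and n = 395, p = 1e-04). With an overlap of at least 50% of both peaks, the shared part was 41.1% of A and 42.3% of B.

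Chromosome Y set the replicates apart. Replicate B had 56 peaks there, covering 93.3 kb, and replicate A had 0 of its 406. A cluster at 56673301 to 56771400, in the heterochromatic long arm, held 34 of them with a top score of 32.74, and a cluster at 11293101 to 11328400 held 10 with a top score of 16.21. Among peaks of B scoring at least 10, 31 lay on chromosome Y and none of these was in A, while 112 of the 113 on other sequences were shared.

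The strength of peaks ran in parallel in both replicates. Shared peaks scored higher than unshared ones, with a median of 9.31 against 4.46 in A (difference 4.85, n = 269 and 137) and of 8.75 against 4.92 in B (difference 3.83, n = 259 and 136; two-sided permutation test, p = 1e-05 for both, the smallest it can give). Shared peaks were also wider, with a median of 900 against 300 bp in A and 800 against 300 bp in B. A wider peak meets the limit of 1 bp of overlap more easily, so this difference can follow from the definition of sharing. In A, 19.4% of the peaks of a single 100 bp window were shared, against 74.7% of the wider ones. The score comparison was not matched on width. Over the 227 shared loci the authors' scores of both lists rose together (Spearman's rho 0.854, Pearson's r of the log2 scores 0.906, permutation p = 1e-05 for each). Within rDNA rho was 0.948 over 34 loci, and over the 193 loci elsewhere it was 0.848. Without the 2 loci farthest from the median in A, rho was 0.850 and r 0.902. Loci within a cluster are not independent, so these p-values describe the lists, not repeated experiments.

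**Figure D2:**
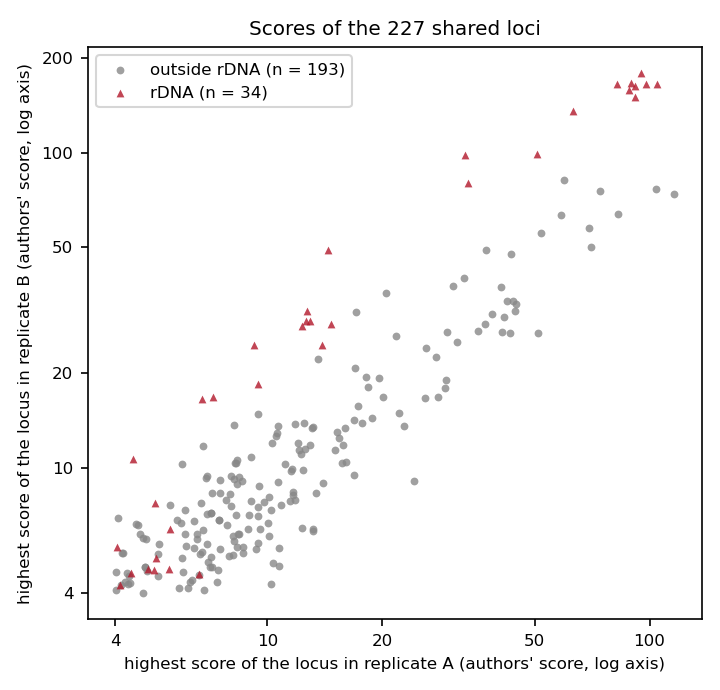
Highest authors' score of each of the 227 shared loci in replicate A (x axis) against replicate B (y axis), both on log axes, with rDNA loci as triangles (n = 34) and the others as circles (n = 193). Scores rise together in both groups (rho 0.948 and 0.848), and the 8 rDNA promoter loci stand at the upper right.

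Peaks were unevenly spread over the chromosomes. Chromosome 21, which carries 4 of the rDNA copies, held 25 of the 148 shared loci on assembled chromosomes against 2.24 by its length (exact binomial test, adjusted p = 1.67e-17). Chromosomes 1 (29 against 11.9), 4 (26 against 9.12), 10 (19 against 6.41) and 16 (17 against 4.33) were also over-represented, with adjusted p from 1.49e-05 to 0.000117. Chromosomes 3, 6, 7, 8, 9, 11, 12, 14, 15 and X held 0 shared loci each and were under-represented (exact binomial test per chromosome against its share of length, two-sided, Benjamini-Hochberg over 24 chromosomes). Replicate B alone was also over-represented on chromosome Y, with 56 of 283 peaks against 5.24 (exact binomial test, adjusted p = 3.06e-38). Counted as clusters, a choice made after the data were seen, only chromosomes 21 and 22 were over-represented and 0 under-represented. The calls of over-representation on chromosomes 1, 4, 10 and 16 thus ended. The 36 clusters on assembled chromosomes were too few for a shortfall on any chromosome to pass, so they do not bear on under-representation. A549 is aneuploid and its copy number was not used here, and gaps in the assembly count as length.

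Peaks avoided genes. Of the shared loci on assembled chromosomes, 81.8% lay more than 1 kb outside any annotated gene, against 44.4% by random placement, and 9.46% lay in a gene body against 49.3% (two-sided placement test, adjusted p = 0.0003 for both, n = 148). The replicates alone gave 75.7% (A, n = 255) and 82.7% (B, n = 283) outside genes, and 14.5% and 9.89% in gene bodies, all at adjusted p = 0.0003. Counted as clusters called in both replicates, a choice made after the data were seen, 7 of 36 lay in a gene body (19.4% against 48.2%, n = 36, adjusted p = 0.0012). With protein-coding genes only, 1.35% of the shared loci lay in a gene body, and with a gene end window of 5 kb 5.41%. Within 1 kb of a gene end lay 8.78% of the shared loci against 6.27% by placement, which did not pass the threshold (n = 148, adjusted p = 0.270). Gene strand and exons were not used here, so promoters, exons and introns were not told apart. Of the same 148 loci, 95.9% lay within 5 Mb of the longest gene-free stretch of their chromosome, against 15.2% by placement. Placement was not matched on region, so the shortfall in genes is not a separate result from that gathering.

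The fixed gene lists asked whether peaks fell at genes of any pathway or family. Of 21 lists, 2 passed the threshold. The list of transfer, ribosomal, small nuclear and small nucleolar RNA genes had 12 of its 1800 members at a shared locus against 1.14 by placement (n = 148 loci, adjusted p = 0.0147), and all 12 were the 45S, 18S, 5.8S and 28S genes of the 3 complete chromosome 21 copies, such as RNA45SN1, RNA18SN1, RNA28SN1, RNA5-8SN1 and RNA45SN2. Long genes of at least 300 kb were hit less often than by placement, with 2 of 773 at a shared locus against 18.3 (n = 148, adjusted p = 0.0042). These 2, RANBP2, which encodes a nuclear pore protein, and SH3RF3, hold the same low-scoring locus on chromosome 2 at 109199301 to 109199700, in a part where their annotated spans overlap. Replicate A had 7 long genes with a peak, among them CACNA1C, BCAS3 and NELL2, and B had 2. The other 19 lists had 0 members at a shared locus: histone genes, zinc finger genes, olfactory receptors, ribosomal protein genes, protocadherins, keratins, solute carriers, ERBB and RAS signalling, p53 and apoptosis, lung epithelial genes, the NRF2 programme, heparan sulfate proteoglycans, nucleolar and rRNA synthesis proteins, the cell cycle, chromatin and DNA methylation, DNA repair, membrane traffic, and haematopoietic and neuronal markers. Placement gave at most 1.28 members for any of these 19 lists (solute carriers), so a shortfall was not detectable, and RPS7, a ribosomal protein gene with a peak in B only, was the only member with a peak in either replicate. When all peaks of a chromosome were shifted together, neither list passed. The 12 RNA genes then stood against 0.547, so the excess stayed but not the call (n = 148, adjusted p = 0.0924), while the 2 long genes stood against 3.28, so most of the shortfall was gone (n = 148, adjusted p = 1.00). Without the rDNA regions the RNA gene list had 0 members.

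Peaks gathered inside or beside long gene-free stretches, which hold the centromere on most chromosomes, rather than at chromosome ends. The annotation used here marks no centromeres, so the longest stretch of each chromosome without an annotated gene was taken as a landmark, a choice made after the data were seen; on chromosome 1 it is 21.7 Mb long and on chromosome 16 10.4 Mb. On chromosomes 13, 15 and Y that stretch lies on the long arm, away from the centromere, so there the landmark does not mark it. Within 1 Mb of that stretch lay 63.5% of the shared loci against 7.19% by placement, 49.8% of A against 7.17% and 59.7% of B against 16.4% (two-sided placement test, n = 148, n = 255 and n = 283, p = 0.0002 for each, the smallest it can give). Without chromosome Y, replicate B had 56.4% there against 6.87%. Within 1 Mb of a chromosome end lay 2.03% of the shared loci against 2.00% by placement (n = 148, p = 1.00) and 2.75% of A against 2.09% (n = 255, p = 0.571). Within 5 Mb of an end, a limit fixed beforehand, the same 2.03% of shared loci stood against 10.1%, a shortfall past the threshold (n = 148, p = 0.0006). Within 1 Mb replicate B had 16.6% against 2.29% (n = 283, p = 0.0002), because the large cluster on chromosome Y lies within 1 Mb of its end; without chromosome Y it had 3.96% (p = 0.0782).

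**Figure D3:**
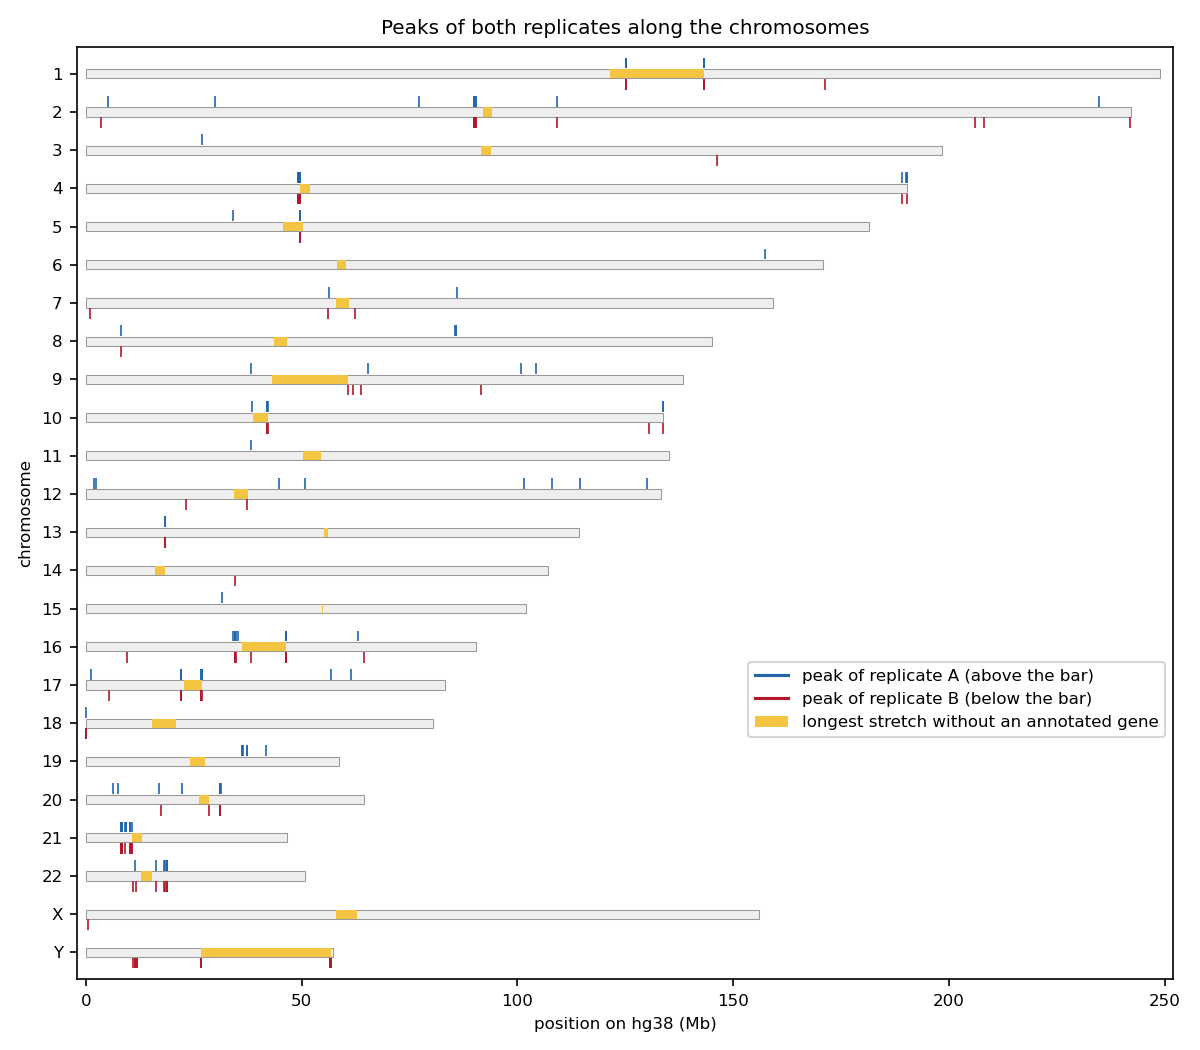
Peaks on the assembled chromosomes (y axis) by position on hg38 in Mb (x axis), with replicate A above and replicate B below each bar and the longest stretch without an annotated gene in yellow. Of the shared loci, 63.5% lie within 1 Mb of that stretch, and chromosome Y has 56 peaks of B and 0 of A.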

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

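The runs without rDNA, without the scaffold copies of rDNA, without chromosome Y, by clusters, with placement within clusters and on the gene-free stretch were chosen after the data were seen. Each setting was counted for every result it was run on. Of these pairs of result and setting, among settings fixed before the data were examined, 54 kept their direction and side of the threshold (or stayed within 1.5 times for counts) and 9 did not. Among pairs with a setting added later 27 did and 6 did not. The pairs rest on the same 2 lists, so they are not independent. The shared part of A ran from 41.1% (50% of both peaks) to 85.5% (within 10 kb) and that of B from 42.3% to 78.5%, all past the threshold. Score differences, the correlation and the classes gene body and outside genes kept their calls under every alternative run. By clusters, 2 chromosomes (21 and 22) were over-represented and 0 under-represented, with fewer units tested, too few to show a shortfall. Single chromosomes also changed in settings fixed beforehand. Over-representation was added for chromosome 20 in each replicate alone, 17 in A, Y in B and 22 in the top 50% by score. Under-representation was lost for chromosome 12 in A and for 14 and 15 in the top 50%. It was added for 5 and 13 in each replicate, 18 and Y in A, and 19 in B. Loci within 1 kb of a gene end came to 12.1% in the top 50% by score (past the threshold), and lay below placement with protein-coding genes only (0%), with a 5 kb window (19.6%), without rDNA (3.10%) and by clusters (5.56%); rDNA genes make up most of that class, and the other causes were not tested. The gene lists past the threshold numbered 1 with protein-coding genes only, 0 with 1 shift per chromosome and 1 without rDNA. Under that shift the 12 RNA genes (against 0.547) and the 2 long genes (against 3.28) did not pass, and peaks of a cluster then move as 1 unit; without rDNA the RNA gene list had 0. The share near chromosome ends ran from 2.75% to 16.6% with 1 replicate alone, where chromosome Y of B makes the difference, and with a 5 Mb limit 2.03% lay below the 10.1% of placement, past the threshold (n = 148, p = 0.0006; the cause was not tested). Matching placement on GC content, leaving out soft-masked peaks, leaving out gaps and the sequence features were not run, as they need a genome sequence. No paired analysis was possible because the input libraries, which share the letters A and B with the captures, were not analysed here. Read depth is not known from the lists, so what it limits could not be judged; peaks near a score of 4 were shared least often.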

Other observations

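The tests on isolated peaks, on the rDNA unit, on peak length, on chromosome Y and on repeat copies were chosen after those results were seen; the count by clusters was fixed before its own result was seen. Away from the clusters, 43 peaks of A and 27 of B stood alone, with no other peak of either list within 50 kb. They were weak and narrow, with a median score of 4.15 and a median width of 100 bp in A, and of 4.53 and 200 bp in B. In A, 13 of the 41 isolated peaks on assembled chromosomes lay in a gene body (31.7% against 52.8% by placement, placement test, n = 41, adjusted p = 0.0300), and in B 8 of 27 did (29.6% against 49.5%, n = 27, adjusted p = 0.0840). In A they included CEACAM5, which encodes a cell adhesion antigen of epithelial cells, the calcium channel genes CACNA1C and CACNA2D4, and ABR. In B they included RPS7, ADAP1, PCSK2 and NFIL3.

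In both replicates the 45S copies with separate peaks had their highest peak at the promoter and the 5′ external transcribed spacer, and peaks over rDNA were longer in B. A lower calling limit in B at all loci would lengthen other peaks of like score too. Shared loci outside rDNA had a median log2 ratio of covered length, B over A, of -0.067 (62 longer in B, 100 longer in A), against 0.50 in rDNA (34 loci, which share reads, permutation p = 2e-05). Scores differed as well. The rDNA promoter peaks had means of 92.6 in A and 164 in B. In clusters of at least 10 peaks elsewhere called in both lists, the top score was lower in B except on chromosome 16. Examples are 82.81 in A and 63.7 in B on chromosome 4, and 38.6 and 30.67 on chromosome 10. On chromosome 16 the top scores were 59.74 and 81.99 in the cluster at 46381301, and 30.5 and 37.7 in that at 34572101. Lengths were not matched on score, so they cannot decide on the calling limit. Copy number of the rDNA array alone would raise the whole unit alike. In the 9 cases with separate peaks (6 on chromosome 21) the promoter peak stood at least 2.37 log2 score units above the mean from the 18S start to the 28S end. Bases without a peak have no score and were given the lowest score of the list in that mean. The peak over the 28S end was also lower than the promoter peak but closer to it, such as 98.91 against 149.64 in RNA45SN1 of B. The gap of at least 2.37 is beyond 2 SD of the difference between equal peaks. That SD came from a scatter of 0.42 log2 score units in each list over the 193 shared loci outside rDNA. This scatter is between the lists at the same locus, and the spread between places within a list was not measured. Copy number alone is therefore not excluded, and RNA45SN4 in B, with 1 peak over both, could not be tested. GC content, the placing of reads among copies, unequal input over the unit and a preference of the peptide for the promoter end were not tested and stay open.

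The peaks on chromosome Y were in B only. A miss by the score threshold in A would leave out like peaks elsewhere; from peaks of B with matching scores on other sequences, 47.1 of the 56 Y peaks would have been found in A, and 0 were. A reference or alignment without Y in replicate A, and cells without Y in replicate A, both predict the 0 peaks of A seen there, and the peak lists hold no value that separates them, so they cannot be told apart. The input libraries, not analysed here, would bear on both. No biological explanation was tested, because the design names no difference between A and B.

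Most of the 148 shared loci on assembled chromosomes lay inside or beside gene-free stretches. Neighbouring peaks counted many times could have made this excess. Counted as clusters called in both replicates, 15 of 36 (41.7%) still lay within 1 Mb of the longest gene-free stretch against 6.85% by placement (placement test, n = 36, p = 0.0002). Some of these clusters lie by the same stretch, such as those on chromosome 5 at 49599501 to 49603200 and 49656201 to 49667500. Joining therefore lessens the counting of neighbours but does not remove it, and the p-value treats clusters as independent. Repeats present in more copies than in the reference, with or without the peptide, may give the same picture. Within 5 Mb of such a stretch, where long satellite arrays are shortened in the assembly, lay 95.9% of the 148 loci against 15.2% by placement. These loci include the rDNA of chromosome 21, and the share in satellite sequence was not measured. Without the input, repeat copy number and a preference of the peptide for this chromatin cannot be told apart. No biological explanation was tested.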
